A study of Caenorhabditis elegans with 8 samples.

How the data were processed

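Polyadenylated RNA of whole hermaphrodites was sequenced in 8 libraries, which the labels place in 4 groups of n = 2. The genotypes were daf-2; hzl-1 and daf-2; aak(0); hzl-1, where aak(0) stands for loss of both AMPK catalytic subunit genes, aak-1 and aak-2. Each genotype was collected as dauers, the arrested larval stage, after 96 h at 25 °C and as post-dauers after 192 h. The labels number the 2 libraries of a group but do not say that they came from separate cultures, so the p-values given here may measure technical spread. Libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols, and read as pairs of at most 80 nt. The strandedness of the libraries is not stated, so reads of overlapping genes on opposite strands may be mixed.

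The authors deposited a table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for all 8 libraries, with 2 decimals per value. They also deposited a table for each background, holding count signal per library divided by a size factor. In those tables the deposited log2 fold changes are dauer minus post-dauer, per the file headers and the group means beside them. The p-values there, raw and adjusted, come from the authors' DESeq2 test, per the file headers. Trimmomatic 0.35, STAR 2.7.1a, RSEM (no version) and DESeq2 1.30.1 with the build WBcel235 were named per the submitters' processing notes, which give no order or role for these tools and no annotation release. The files held 46904 genes. An Ensembl release 115 annotation of the same build had 46817 genes, and 69.1% of its genes had the same start and end, so coordinates are given as the files list them.

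The design, fixed before the data were examined, assumed deposited raw counts. The files held another unit, FPKM beside size-factor-divided counts, so the test that the design named for FPKM was used: limma 3.58.1 (trend) on log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the 8 libraries were tested, 15365 in number. All 8 libraries were fitted together with a mean per group and no replicate block, which left 4 residual degrees of freedom and a prior of 2.69. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. A fold change on log2(FPKM + 1) understates the change of genes with low FPKM. Where a group was listed at 0, the report gives no fold change against it, and fitted values in the closing section rest on the pseudocount or prior count.

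Within the tables of each background, every deposited value above 0 was a whole multiple of the smallest value of its library, at a tolerance of 1e-06. The share that came out whole was 100% in each library, so whole read numbers were recovered and summed to 13.99 and 18.72 M reads for the daf-2; hzl-1 dauers, 15.61 and 18.75 M reads for their post-dauers, 23.41 and 25.34 M reads for the aak(0) dauers and 20.65 and 26.98 M reads for the aak(0) post-dauers. On these reads edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) tested 17050 genes, and its results are printed beside those of limma. Genes called on recovered reads are counted under each comparison. Percentages of reads were computed from the recovered reads of all genes.

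The comparisons made were 5 in number. Both stage comparisons took post-dauer minus dauer within a background, and both genotype comparisons took daf-2; aak(0); hzl-1 minus daf-2; hzl-1 within a stage. The interaction was the stage change in the aak(0) background minus that in daf-2; hzl-1. Animals with functional hzl-1 were not analysed here, so an effect of hzl-1 itself was outside the design.

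For gene lists, 36 were written by symbol before the data were examined, with 898 symbols, of which 14 matched no gene in the files (cco-1, cco-2, cdc-20, cde-1, col-6, daf-21, dod-11, dod-8, ehn-1, mut-8, rde-3, rpl-40, rpl-41 and wago-3). Lists were tested with limma camera at a preset correlation of 0.01 when at least 5 members were tested, with adjustment over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. With an estimated correlation no list was called in any comparison (0 of 35), and that adjusted p is printed with each list. Members called were counted with adjustment over all genes and again adjusted over the list alone. Male-enriched somatic genes were not tested, since 3 of the 16 matched genes passed the FPKM filter, and their highest FPKM in any library was 188 for nlp-8.

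Genes to be named were chosen per comparison by a rule written before the data were examined. It took the 6 largest rises and the 6 largest falls among called genes with a gene name and no overlap of the groups' values, with at most 2 genes sharing the letters of their name, and a mean FPKM of at least 5 in place of a limit on counts. It also took the 3 members with the smallest adjusted p in each of the 9 lists with the highest share called and in any other list called, and aak-1, aak-2, hzl-1 and daf-2 always.

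Scripts were first tested on simulated data with known answers. About 200 genes were changed per comparison, fewer than the data had calls. Of genes changed 4-fold, limma recovered 41.7%, 51.5%, 49.0%, 45.4% and 1.00% in the comparisons in the order above, and edgeR 50.5%, 64.6%, 60.2%, 58.8% and 1.01%. Between 4 and 13 unchanged genes were called by limma in each. A gene changed 2-fold was recovered by limma in at most 3.13% of cases, so a gene that was not called may still differ.

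Several alternatives were run, and the closing section gives their effect: edgeR with RLE scaling, library totals or no filter, DESeq2 1.42.0, limma on FPKM divided by TMM factors or rescaled to reads outside rRNA, a pseudocount of 0.1, no FPKM filter, the compared libraries alone, a replicate block, and each library left out in turn. Correlations between the deviations of same-numbered libraries ran from -0.258 to 0.0147, so replicate numbers do not pair across groups. Last digits of DESeq2 output varied between reruns, so its adjusted p-values are stored rounded to 2 significant digits, after calls were made. Computations used R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.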

Results

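Transcripts of whole daf-2 mutant hermaphrodites were measured by RNA sequencing at 2 stages and in 2 genotypes. Both genotypes carried mutations in daf-2, the insulin/IGF receptor gene whose loss sends larvae into dauer at 25 °C, and in hzl-1 (C44H9.4). The first is labelled daf-2; hzl-1 and written daf-2 hzl-1 here. In the second, aak-1 and aak-2, the catalytic subunit genes of the energy sensor AMPK, were lost as well, and these libraries are labelled aak(0). Each of the 4 groups held n = 2 libraries, with 13.99 to 26.98 M recovered reads. Reads of rRNA took 12.8% of the first daf-2 hzl-1 dauer library, the shallowest, and 3.49% of the second. They took 0.711% and 0.559% in daf-2 hzl-1 post-dauers, 9.61% and 1.12% in aak(0) dauers, and 0.806% and 5.40% in aak(0) post-dauers. Replicates had a Spearman correlation of 0.973 in daf-2 hzl-1 post-dauers and 0.976 in aak(0) dauers. It was 0.921 in daf-2 hzl-1 dauers and 0.923 in aak(0) post-dauers, where 11.99% and 17.2% of genes stood more than 2 times apart. Means are given as FPKM ± SD and log2 changes ± SE, each with n = 2 libraries per group.

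**Figure D1:**
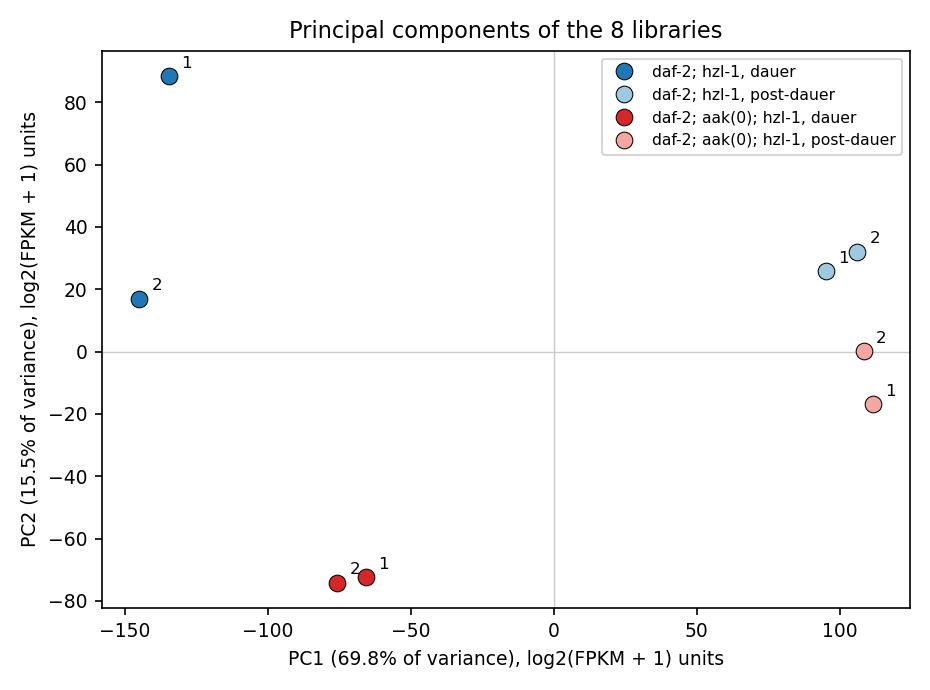
Principal components of log2(FPKM + 1) over the tested genes, 1 point per library, with component 1 (69.8% of variance) against component 2 (15.5%). Component 1 parted dauers from post-dauers, and on component 2 the aak(0) dauers lay at -72.5 and -74.1 while the daf-2 hzl-1 dauers lay at 88.4 and 17.01.

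Of the targeted genes, aak-1 (WBGene00019801, III:8756995-8761101, build WBcel235) stood at 3.15 ± 0.0636 FPKM in daf-2 hzl-1 dauers and 8.67 ± 0.113 in their post-dauers. It stood at 12.35 ± 3.34 in aak(0) dauers and 7.44 ± 0.396 in aak(0) post-dauers. Transcripts of aak-1 rose from dauer to post-dauer in daf-2 hzl-1 (log2 1.22 ± 0.24, limma adjusted p = 0.00366) and were higher in aak(0) dauers than in daf-2 hzl-1 dauers (log2 1.66 ± 0.24, limma adjusted p = 0.00399). The other catalytic subunit gene, aak-2 (WBGene00020142, X:16796087-16803357), measured 39.6 ± 5.66, 19.3 ± 1.28, 43.5 ± 7.93 and 9.62 ± 0.318 FPKM in the same order. From dauer to post-dauer aak-2 fell by log2 0.99 ± 0.20 in daf-2 hzl-1 (limma adjusted p = 0.00410) and by log2 2.06 ± 0.20 in aak(0) (limma adjusted p = 0.000405). In post-dauers aak-2 was not called lower in aak(0) by limma (log2 -0.93 ± 0.20, adjusted p = 0.0514), while edgeR called it (log2 -1.02, adjusted p = 0.0414). No group stood near 0 for either gene, and gene-level values do not see a deletion inside a gene. These transcripts therefore check no label, and directions in the genotype comparisons rest on the libraries labelled aak(0). Exons of aak-1 overlap sma-2 over 100 nt and those of aak-2 overlap mec-4 over 78 nt on the opposite strand.

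The gene hzl-1 (WBGene00008099, V:12835708-12839783) was low throughout, at 0.545 ± 0.0636, 0.955 ± 0.686, 0.96 ± 0.099 and 1.89 ± 1.97 FPKM, from 28 to 231 reads per library. No comparison called hzl-1 by limma (adjusted p = 0.626, 0.573, 0.645 and 0.678 for stage and genotype and 0.952 for the interaction). Without aak(0) post-dauer library 2 its rise from dauer to post-dauer in aak(0) was called (log2 1.13, adjusted p = 0.0389). For daf-2 (WBGene00000898, III:2995487-3040860) the means were 31.4 ± 2.41, 25.7 ± 3.28, 36.7 ± 0.771 and 23.5 ± 13.7 FPKM. Limma called no difference for daf-2 either (adjusted p = 0.517, 0.132, 0.691, 0.752 and 0.573). Without aak(0) post-dauer library 1, daf-2 was called lower in aak(0) post-dauers than in aak(0) dauers (log2 -1.35, adjusted p = 0.00372) and than in daf-2 hzl-1 post-dauers (log2 -0.85, adjusted p = 0.0477). Its interaction was called in the same fit (log2 -1.06, adjusted p = 0.0315).

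The stage comparison in daf-2 hzl-1 asked which transcripts change when animals with intact aak genes leave the arrest. Vitellogenin transcripts, which encode the yolk proteins made by the adult intestine, rose the most. The largest rise was that of vit-6, from 0.26 ± 0.0141 to 5519 ± 127 FPKM (log2 12.097 ± 0.53, limma adjusted p = 1.19e-05). The uterine protein gene ule-4 rose from 0.315 ± 0.445 to 2311 ± 499 FPKM (log2 10.81 ± 0.29, limma adjusted p = 5.24e-06). Its relative ule-5, listed at 0 in dauers, stood at 937 ± 208.4 FPKM in post-dauers. Adult collagen col-140 rose from 0.425 ± 0.00707 to 2237 ± 106 FPKM (log2 10.62 ± 1.18, limma adjusted p = 3.21e-04). Transcripts of the secreted SCP-like protein gene scl-11 fell from 2176 ± 316 to 19.4 ± 10.2 FPKM (log2 -6.83 ± 0.34, limma adjusted p = 1.75e-05). Those of scl-12 fell from 1594 ± 84.6 to 15.8 ± 10.4 FPKM (log2 -6.72 ± 0.52, limma adjusted p = 7.74e-05). The groundhog-like gene grl-23 fell from 559 ± 563 to 3.42 ± 0.17 FPKM (log2 -6.48 ± 0.75, limma adjusted p = 3.74e-04), with its dauer libraries far apart. Over 15365 genes limma called 10335 (6060 higher, 4275 lower), 8607 of them by more than log2 1, and edgeR called 11681 (5648 higher, 6033 lower). The share of higher calls, 58.6%, was 48.4% by edgeR with TMM scaling. The median gene moved from log2 0.34 to -0.01 between these scalings, so list medians are also given relative to all genes. In the authors' deposited table of this background 10875 genes had an adjusted p under 0.05, 5677 of them higher in post-dauers.

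Germline and replication lists rose from dauer to post-dauer in daf-2 hzl-1. Every tested oocyte and eggshell gene rose, 30 of 30, also adjusted over the list alone and by edgeR. The median oocyte gene had a log2 change of 5.497, 5.16 relative to all genes (limma camera adjusted p = 6.4e-13, adjusted p = 0.41 with an estimated correlation). Among them cbd-1, for a chitin-binding eggshell protein, rose from 3.85 ± 0.177 to 611 ± 43.9 FPKM (log2 6.98 ± 0.17, limma adjusted p = 4.38e-06). The polarity gene mex-6 rose from 3.94 ± 0.113 to 236 ± 1.35 FPKM (log2 5.59 ± 0.13, limma adjusted p = 4.38e-06). All 28 major sperm proteins rose, again 28 adjusted over the list alone and 28 by edgeR. The median major sperm protein had a log2 change of 5.27, 4.93 relative to all genes (limma camera adjusted p = 1.4e-11, adjusted p = 0.48 with an estimated correlation). Of these msp-51 rose from 3.31 ± 0.658 to 462 ± 97.9 FPKM (log2 6.74 ± 0.19, limma adjusted p = 5.24e-06), though near-identical sequences leave single msp values uncertain. DNA replication and cell cycle genes rose in 33 of 34 cases, 34 adjusted over the list alone. The median replication gene had a log2 change of 2.42, 2.08 relative to all genes (limma camera adjusted p = 1.7e-09, adjusted p = 0.48 with an estimated correlation). The ribonucleotide reductase gene rnr-2 rose from 18.4 ± 1.05 to 456 ± 32.01 FPKM (log2 4.56 ± 0.13, limma adjusted p = 5.24e-06). P granule genes, a list named for germ granules, rose in 19 of 21 cases, the same 19 adjusted over the list alone. The median P granule gene had a log2 change of 2.63, 2.29 relative to all genes (limma camera adjusted p = 3.0e-06, adjusted p = 0.48 with an estimated correlation). Their member meg-1 rose from 0.165 ± 0.191 to 65.7 ± 4.31 FPKM (log2 5.85 ± 0.19, limma adjusted p = 5.63e-06). In the list of germline stem cell and meiosis genes 31 of 38 rose and 1 fell, 33 and 2 adjusted over the list alone. The median germline gene had a log2 change of 1.46, 1.12 relative to all genes (limma camera adjusted p = 1.1e-04, adjusted p = 0.51 with an estimated correlation). The translational repressor gene gld-1 rose from 15.3 ± 3.01 to 363 ± 32.3 FPKM (log2 4.49 ± 0.17, limma adjusted p = 7.39e-06). Sperm genes other than MSP rose in 19 of 24 cases and fell in 1, the same adjusted over the list alone. The median other sperm gene had a log2 change of 1.85, 1.51 relative to all genes (limma camera adjusted p = 0.00205, adjusted p = 0.68 with an estimated correlation).

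Somatic lists of the adult rose as well in daf-2 hzl-1. All 6 vitellogenins rose, 6 adjusted over the list alone and 6 by edgeR. The median vitellogenin gene had a log2 change of 11.41, 11.07 relative to all genes (limma camera adjusted p = 7.0e-05, adjusted p = 0.48 with an estimated correlation). All 9 adult cuticle genes rose, 9 adjusted over the list alone. The median adult cuticle gene had a log2 change of 3.92, 3.58 relative to all genes (limma camera adjusted p = 2.5e-04, adjusted p = 0.48 with an estimated correlation). Intestine markers rose in 17 of 24 cases and fell in 2, unchanged adjusted over the list alone, and 1 fell without post-dauer library 2. The median intestine marker had a log2 change of 2.39, 2.06 relative to all genes (limma camera adjusted p = 0.00179, adjusted p = 0.68 with an estimated correlation). The gut protease gene cpr-5 rose from 0.535 ± 0.757 to 313 ± 8.59 FPKM (log2 7.77 ± 0.36, limma adjusted p = 1.41e-05). Of the innate immunity genes 22 of 30 rose and 5 fell, the same adjusted over the list alone. The median immunity gene had a log2 change of 2.82, 2.49 relative to all genes (limma camera adjusted p = 0.00525, adjusted p = 0.67 with an estimated correlation). The antibacterial saposin-like gene spp-1 rose from 16.8 ± 3.78 to 272 ± 23.7 FPKM (log2 3.95 ± 0.19, limma adjusted p = 1.50e-05). Molting and larval cuticle genes rose in 11 of 26 cases and fell in 1, the same adjusted over the list alone. Without dauer library 2, 23 of them rose, and without dauer library 1, 2 fell. The median molting gene had a log2 change of 1.64, 1.31 relative to all genes (limma camera adjusted p = 0.00666, adjusted p = 0.68 with an estimated correlation). Their collagen gene dpy-5 rose from 0.20 ± 0.156 to 53.7 ± 25.9 FPKM (log2 5.43 ± 0.32, limma adjusted p = 3.10e-05).

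Neuronal, ribosomal and mitochondrial lists fell from dauer to post-dauer in daf-2 hzl-1. FPKM is a share of whole-animal RNA, so a falling list need not mean lower expression per cell. All 30 FMRFamide-like neuropeptide genes fell, 30 adjusted over the list alone and 30 by edgeR. The median FMRFamide-like gene had a log2 change of -3.67, -4.01 relative to all genes (limma camera adjusted p = 4.1e-14, adjusted p = 0.48 with an estimated correlation). The sleep neuropeptide gene flp-11 fell from 265 ± 8.4004 to 11.9 ± 2.64 FPKM (log2 -4.38 ± 0.17, limma adjusted p = 9.10e-06). Other neuron markers fell in 24 of 27 cases and rose in 1, the same adjusted over the list alone. The median neuron marker had a log2 change of -2.15, -2.48 relative to all genes (limma camera adjusted p = 6.1e-08, adjusted p = 0.48 with an estimated correlation). The gene sbt-1, for a chaperone of neuropeptide processing, fell from 778 ± 111 to 47.5 ± 13.7 FPKM (log2 -4.03 ± 0.22, limma adjusted p = 2.34e-05). Cytosolic ribosomal protein genes fell in 67 of 78 cases and rose in 2, 70 and 2 adjusted over the list alone and 68 and 1 by edgeR. Without post-dauer library 2 the fallen ribosomal genes numbered 34. The median ribosomal protein gene had a log2 change of -0.99, -1.33 relative to all genes (limma camera adjusted p = 1.3e-10, adjusted p = 0.68 with an estimated correlation). Among them rpl-24.2 fell from 1144 ± 275 to 232 ± 11.8 FPKM (log2 -2.28 ± 0.20, limma adjusted p = 1.16e-04). Mitochondrially encoded genes fell in 10 of 14 cases and rose in 3, the same adjusted over the list alone. By edgeR 10 fell, and without post-dauer library 2 limma called 1 higher. The median mitochondrial gene had a log2 change of -1.22, -1.55 relative to all genes (limma camera adjusted p = 0.00666, adjusted p = 0.67 with an estimated correlation). The complex I gene nduo-2 fell from 454 ± 36.4 to 52.4 ± 4.57 FPKM (log2 -3.09 ± 0.19, limma adjusted p = 3.22e-05).

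Dauer regulators and dauer collagens fell in daf-2 hzl-1 with more spread. Dauer formation genes fell in 12 of 23 cases and rose in 4, the same adjusted over the list alone, and 7 fell without post-dauer library 1. The median dauer formation gene had a log2 change of -0.67, -1.01 relative to all genes (limma camera adjusted p = 0.0222, adjusted p = 0.68 with an estimated correlation). The FOXO gene daf-16 fell from 202 ± 14.6 to 56.6 ± 6.96 FPKM (log2 -1.82 ± 0.17, limma adjusted p = 1.43e-04). The nuclear receptor gene daf-12, which decides between arrest and growth, fell from 77.1 ± 8.59 to 6.72 ± 1.29 FPKM (log2 -3.34 ± 0.27, limma adjusted p = 8.74e-05). Insulin-like peptide genes fell in 14 of 24 cases and rose in 5, the same adjusted over the list alone. The median insulin-like gene had a log2 change of -1.82, -2.15 relative to all genes (limma camera adjusted p = 0.0101, adjusted p = 0.48 with an estimated correlation). The peptide gene ins-18 fell from 92.4 ± 11.6 to 6.30 ± 0.898 FPKM (log2 -3.68 ± 0.22, limma adjusted p = 3.17e-05). Of 7 dauer cuticle genes 4 fell, 4 adjusted over the list alone and 7 by edgeR. That count was 7 without dauer library 1 and 0 without either post-dauer library. The median dauer cuticle gene had a log2 change of -4.12, -4.46 relative to all genes (limma camera adjusted p = 0.0441, adjusted p = 0.68 with an estimated correlation). The median FPKM of the list was 2.31 in dauer library 1 and 272 in library 2, so these collagens differed between replicates as much as between stages. The dauer collagen col-40 fell from 466 ± 641 to 0.275 ± 0.0636 FPKM (log2 -6.43 ± 1.68, limma adjusted p = 0.0129). It lost its call without post-dauer library 1 (log2 -6.38, adjusted p = 0.0583) or 2 (log2 -6.49, adjusted p = 0.05996).

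**Figure D2:**
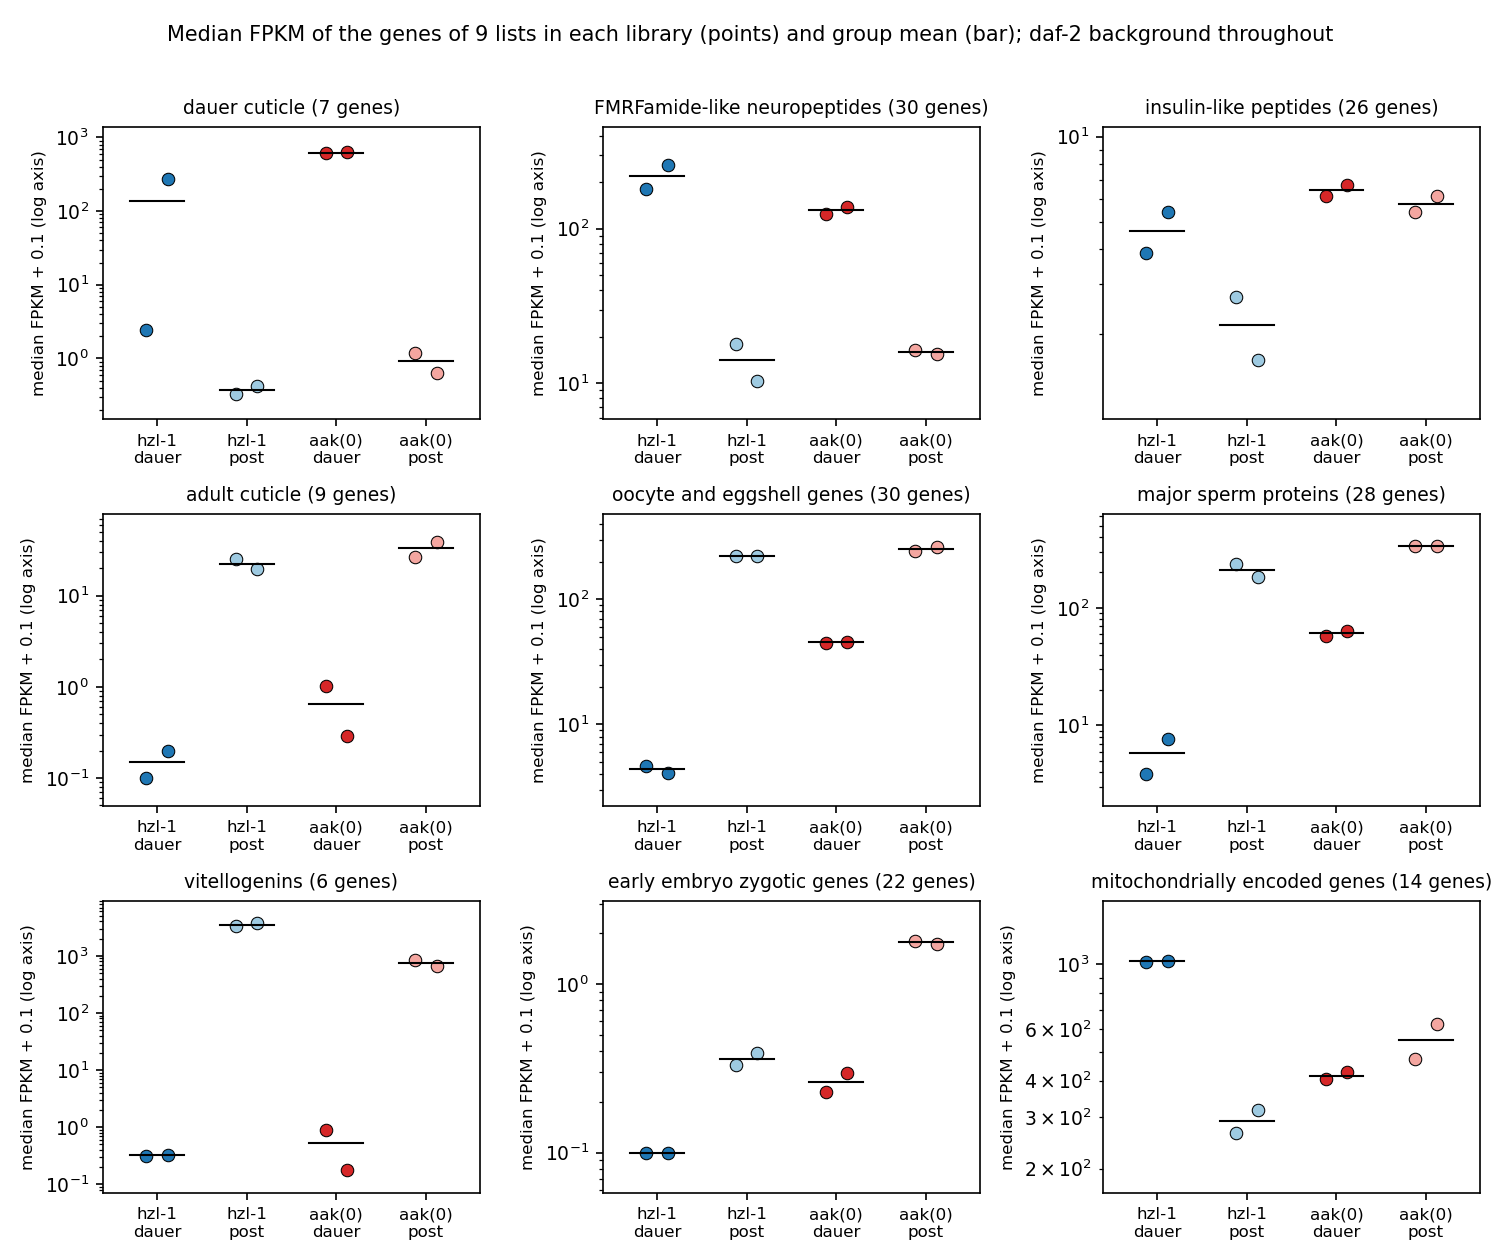
Median FPKM (log axis, 0.1 added) of 9 gene lists in each of the 8 libraries, with points for libraries and bars for group means. In aak(0) dauers the oocyte and eggshell median stood at 45.1 and 45.9 FPKM, against 4.595 and 4.03 in daf-2 hzl-1 dauers and 221 and 222 in their post-dauers.

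The same comparison in aak(0) asked how animals without the aak genes change. Yolk transcripts again rose the most, led by vit-5, from 0.61 ± 0.75 to 1106 ± 211 FPKM (log2 9.50 ± 0.32, limma adjusted p = 3.24e-05). The uterine protein gene ule-1 rose from 0.45 ± 0.0566 to 449 ± 36.6 FPKM (log2 8.28 ± 0.23, limma adjusted p = 1.71e-05). The dauer collagen col-37 fell from 1585 ± 20.1 to 0.075 ± 0.0212 FPKM (log2 -10.53 ± 1.66, limma adjusted p = 0.00241). Its exons overlap ZK863.10 over 225 nt on the opposite strand, so its value is uncertain. Another dauer collagen, col-40, fell from 1883 ± 18.9 to 0.43 ± 0.0141 FPKM (log2 -10.36 ± 1.68, limma adjusted p = 0.00268). The secreted protein gene scl-12 fell from 3035 ± 1013 to 2.06 ± 1.51 FPKM (log2 -10.01 ± 0.52, limma adjusted p = 7.46e-05). The small heat shock protein gene hsp-12.6 fell from 902 ± 48.9 to 20.3 ± 12.5 FPKM (log2 -5.54 ± 0.54, limma adjusted p = 4.09e-04). By limma 8130 of 15365 genes were called (3975 higher, 4155 lower), 6021 of them by more than log2 1, and by edgeR 9350 (4254 higher, 5096 lower). Without aak(0) dauer library 1 or 2 limma called 5263 or 4964. The authors' deposited table of this background had 8614 genes with an adjusted p under 0.05, 4043 of them higher in post-dauers.

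Oocyte and eggshell genes rose in 28 of 30 cases in aak(0), 28 adjusted over the list alone and 28 by edgeR. The median oocyte gene had a log2 change of 2.07, 2.04 relative to all genes (limma camera adjusted p = 1.7e-12, adjusted p = 0.41 with an estimated correlation). For mex-6 the rise was from 45.7 ± 1.27 to 262 ± 11.12 FPKM (log2 2.49 ± 0.13, limma adjusted p = 7.46e-05). All 28 major sperm proteins rose, 28 adjusted over the list alone. The median major sperm protein had a log2 change of 2.71, 2.69 relative to all genes (limma camera adjusted p = 1.7e-12, adjusted p = 0.41 with an estimated correlation). Among the sperm transcripts msp-51 rose from 79.1 ± 3.56 to 723 ± 0.431 FPKM (log2 3.18 ± 0.19, limma adjusted p = 1.06e-04). DNA replication and cell cycle genes rose in 30 of 34 cases, 30 adjusted over the list alone. The median replication gene had a log2 change of 1.52, 1.498 relative to all genes (limma camera adjusted p = 2.3e-10, adjusted p = 0.41 with an estimated correlation). P granule genes rose in 17 of 21 cases, 18 adjusted over the list alone. The median P granule gene had a log2 change of 1.34, 1.32 relative to all genes (limma camera adjusted p = 2.4e-06, adjusted p = 0.41 with an estimated correlation). Germline stem cell and meiosis genes rose in 22 of 38 cases, the same 22 adjusted over the list alone. The median germline gene had a log2 change of 0.88, 0.86 relative to all genes (limma camera adjusted p = 4.5e-06, adjusted p = 0.41 with an estimated correlation). Sperm genes other than MSP rose in 9 of 24 cases, 5 adjusted over the list alone. Without aak(0) dauer library 1 or 2 there were 2, without post-dauer library 1 there were 4 and without library 2 there were 16. The median other sperm gene had a log2 change of 0.46, 0.44 relative to all genes (limma camera adjusted p = 0.0135, adjusted p = 0.75 with an estimated correlation). All 6 vitellogenins rose, 6 adjusted over the list alone. The median vitellogenin gene had a log2 change of 8.66, 8.64 relative to all genes (limma camera adjusted p = 1.8e-06, adjusted p = 0.41 with an estimated correlation). All 9 adult cuticle genes rose too, 9 adjusted over the list alone. The median adult cuticle gene had a log2 change of 3.86, 3.84 relative to all genes (limma camera adjusted p = 3.4e-06, adjusted p = 0.41 with an estimated correlation).

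Neuropeptide transcripts fell in aak(0) as well, in 29 of 30 FMRFamide-like genes, 29 adjusted over the list alone. The median FMRFamide-like gene had a log2 change of -2.66, -2.68 relative to all genes (limma camera adjusted p = 1.7e-12, adjusted p = 0.41 with an estimated correlation). The gene flp-11 fell from 127 ± 5.54 to 23.1 ± 0.276 FPKM (log2 -2.41 ± 0.17, limma adjusted p = 1.78e-04). Neuron markers fell in 22 of 27 cases and rose in 1, 25 and 1 adjusted over the list alone. The median neuron marker had a log2 change of -1.86, -1.89 relative to all genes (limma camera adjusted p = 4.2e-07, adjusted p = 0.41 with an estimated correlation). The neuropeptide convertase gene egl-3 fell from 301 ± 60.01 to 20.5 ± 1.80 FPKM (log2 -3.80 ± 0.26, limma adjusted p = 1.56e-04). Dauer cuticle genes fell in 6 of 7 cases, 6 adjusted over the list alone and 6 by edgeR. The median dauer cuticle gene had a log2 change of -9.05, -9.07 relative to all genes (limma camera adjusted p = 0.0088, adjusted p = 0.75 with an estimated correlation). Cytosolic ribosomal protein genes fell in 52 of 78 cases and rose in 1, 61 and 2 adjusted over the list alone but 6 and 1 by edgeR. Without aak(0) dauer library 1 or 2 the lower genes numbered 21 or 3, without post-dauer library 1 there were 12, and without library 2 the genes that rose were 2. The median ribosomal protein gene had a log2 change of -0.78, -0.81 relative to all genes (limma camera adjusted p = 2.0e-07, adjusted p = 0.75 with an estimated correlation). Mitochondrially encoded genes moved the other way than in daf-2 hzl-1, with 7 of 14 higher and 1 lower, the same adjusted over the list alone. By edgeR 6 were higher, and limma called 2 lower without post-dauer library 2. The median mitochondrial gene had a log2 change of 0.65, 0.63 relative to all genes (limma camera adjusted p = 0.0129, adjusted p = 0.75 with an estimated correlation). The ATP synthase gene atp-6 rose from 732 ± 51.95 to 2353 ± 148 FPKM (log2 1.68 ± 0.16, limma adjusted p = 4.26e-04).

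Changes between the stages in the 2 backgrounds shared no library and had a Pearson r of 0.809 and a Spearman rho of 0.825 over 15365 genes, which are not independent replicates. Genes higher in post-dauers in both numbered 3575, against 1568 for independent lists. Genes lower in both numbered 3322, against 1156, and opposite calls 59, against 2745.

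**Figure D3:**
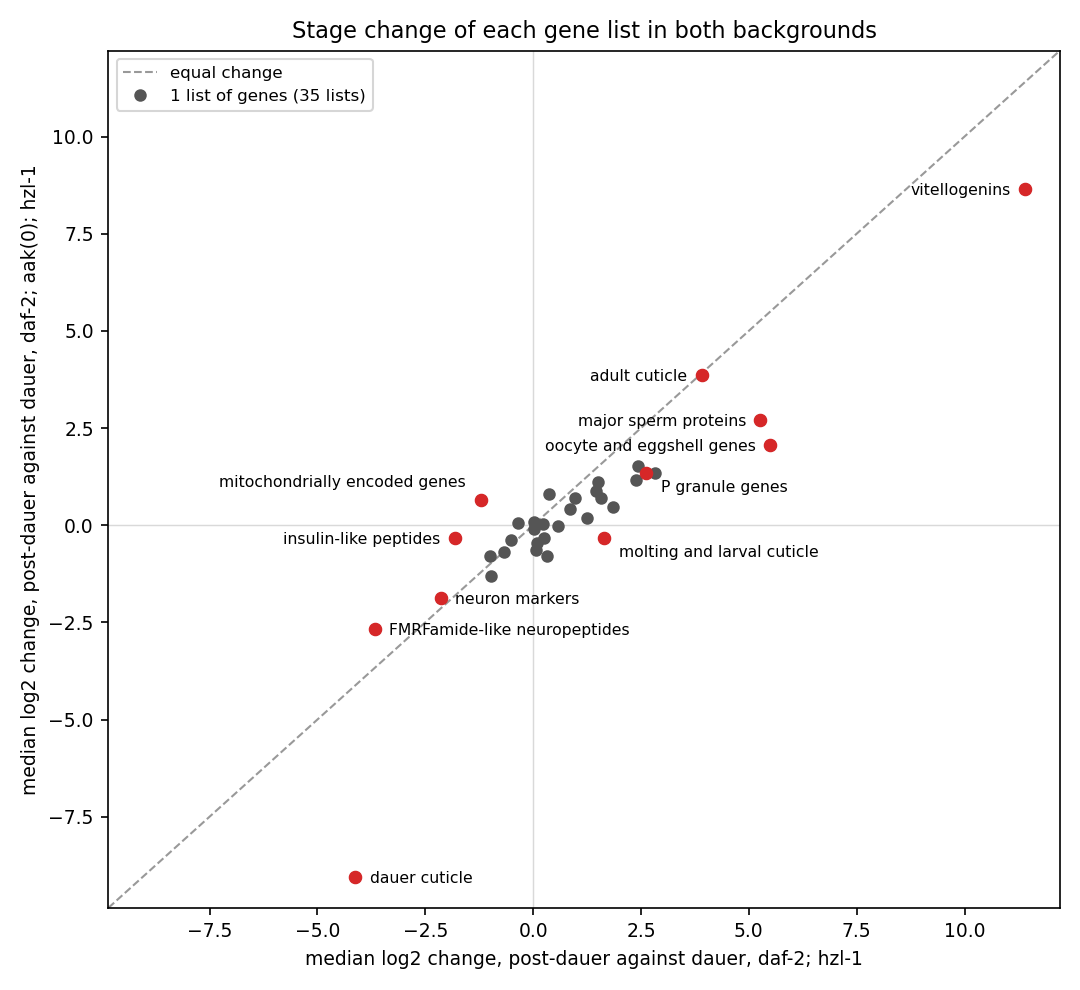
Median log2 change from dauer to post-dauer of each of 35 gene lists, in daf-2 hzl-1 on the horizontal axis and in aak(0) on the vertical axis, with a dashed line of equal change. Oocyte and eggshell genes (5.497 and 2.07) lay off the line, and mitochondrially encoded genes (-1.22 and 0.65) changed sign.

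In dauers the comparison of aak(0) with daf-2 hzl-1 asked what loss of the aak genes changes. In libraries labelled aak(0) the galectin gene lec-10 was higher, from 0.83 ± 0.566 to 115 ± 7.38 FPKM (log2 6.02 ± 0.26, limma adjusted p = 1.68e-04). The cathepsin gene cpr-2 was higher, from 1.38 ± 0.318 to 210.4 ± 5.13 FPKM (log2 6.48 ± 0.45, limma adjusted p = 3.00e-04). So was sdz-24, named for its dependence on SKN-1, from 0.785 ± 1.11 to 72.5 ± 1.25 FPKM (log2 5.52 ± 0.43, limma adjusted p = 4.51e-04). The gene pud-2.1, for a protein abundant in daf-2 mutants, was higher, from 0.635 ± 0.898 to 376 ± 138 FPKM (log2 7.92 ± 0.46, limma adjusted p = 1.89e-04), with a smaller value by edgeR (log2 4.38, adjusted p = 0.0186). Lower in aak(0) dauers was fipr-13, for a small secreted peptide, from 284 ± 13.4 to 40.3 ± 6.99 FPKM (log2 -2.79 ± 0.18, limma adjusted p = 2.42e-04). The neuropeptide gene flp-1 was lower, from 704 ± 88.4 to 140.1 ± 12.32 FPKM (log2 -2.32 ± 0.27, limma adjusted p = 0.0018). The histone genes his-56 and his-46, with identical and so uncertain values, were lower, from 48.8 ± 9.16 to 9.52 ± 0.177 FPKM (log2 -2.23 ± 0.23, limma adjusted p = 0.00118), and edgeR did not test them. Limma called 4464 of 15365 genes (3911 higher, 553 lower), 3246 of them by more than log2 1, and edgeR 3881 (2518 higher, 1363 lower). The share of higher calls was 87.6% as deposited, 64.9% by edgeR with TMM, 58.8% with RLE and 59.9% by DESeq2. The median gene stood at log2 0.41 as deposited and 0.05 with TMM. Without aak(0) dauer library 1 or 2 limma called 1305 or 1414 genes, and without daf-2 hzl-1 dauer library 1 it called 2967.

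Sperm, oocyte, P granule and replication lists stood higher in aak(0) dauers. All 28 major sperm proteins were higher, 28 adjusted over the list alone and 27 by edgeR. The median major sperm protein had a log2 change of 3.25, 2.84 relative to all genes (limma camera adjusted p = 1.5e-15, adjusted p = 0.74 with an estimated correlation). Among them msp-51 was higher, from 3.31 ± 0.658 to 79.1 ± 3.56 FPKM (log2 4.22 ± 0.19, limma adjusted p = 1.68e-04), a value that shared reads leave uncertain. Oocyte and eggshell genes were higher in 27 of 30 cases, 27 adjusted over the list alone and 27 by edgeR. The median oocyte gene had a log2 change of 2.72, 2.31 relative to all genes (limma camera adjusted p = 1.5e-15, adjusted p = 0.29 with an estimated correlation). The eggshell gene cbd-1 was higher, from 3.85 ± 0.177 to 118 ± 4.86 FPKM (log2 4.62 ± 0.17, limma adjusted p = 1.49e-04). The polarity gene mex-6 was higher, from 3.94 ± 0.113 to 45.7 ± 1.27 FPKM (log2 3.24 ± 0.13, limma adjusted p = 1.50e-04). The Nanos gene nos-2, needed in primordial germ cells, was higher, from 1.15 ± 0.0283 to 36.03 ± 0.417 FPKM (log2 4.11 ± 0.15, limma adjusted p = 1.49e-04). Exons of nos-2 overlap him-14 over 83 nt on the opposite strand. DNA replication and cell cycle genes were higher in 23 of 34 cases, 24 adjusted over the list alone and 11 by edgeR. The median replication gene had a log2 change of 0.99, 0.58 relative to all genes (limma camera adjusted p = 5.4e-05, adjusted p = 0.78 with an estimated correlation). The reductase gene rnr-2 was higher, from 18.4 ± 1.05 to 155 ± 6.58 FPKM (log2 3.01 ± 0.13, limma adjusted p = 1.68e-04). P granule genes were higher in 12 of 21 cases, 12 adjusted over the list alone and 7 by edgeR, and in 7 without aak(0) dauer library 1. The median P granule gene had a log2 change of 0.85, 0.44 relative to all genes (limma camera adjusted p = 0.014, adjusted p = 0.79 with an estimated correlation). Camera on recovered reads did not call this list (adjusted p = 0.0553). Their member meg-1 was higher, from 0.165 ± 0.191 to 10.1 ± 0.651 FPKM (log2 3.26 ± 0.19, limma adjusted p = 1.96e-04). Sperm genes other than MSP were higher in 12 of 24 cases, 15 adjusted over the list alone, and in 4 without either aak(0) dauer library. The median other sperm gene had a log2 change of 1.23, 0.82 relative to all genes (limma camera adjusted p = 0.00345, adjusted p = 0.97 with an estimated correlation).

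Vitellogenin transcripts did not follow, with 0 of 6 called by limma or edgeR and 0 at unadjusted p < 0.05 by either, though limma called 2 higher without aak(0) dauer library 2. The median vitellogenin gene had a log2 change of 0.21, -0.20 relative to all genes (limma camera adjusted p = 0.78, adjusted p = 0.98 with an estimated correlation). The list of germline stem cell and meiosis genes was not called as a whole, with 5 higher and 3 lower of 38, 5 and 1 adjusted over the list alone. Without either aak(0) dauer library 2 were higher and 1 lower. The median germline gene had a log2 change of 0.17, -0.24 relative to all genes (limma camera adjusted p = 0.32, adjusted p = 0.98 with an estimated correlation). Camera on recovered reads called this list lower (adjusted p = 0.048).

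Lower in aak(0) dauers were mitochondrial and neuropeptide transcripts. Mitochondrially encoded genes were lower in 12 of 14 cases, 12 adjusted over the list alone and 11 by edgeR, and in 6 and 7 without aak(0) dauer library 1 and 2. The median mitochondrial gene had a log2 change of -1.17, -1.58 relative to all genes (limma camera adjusted p = 1.9e-14, adjusted p = 0.44 with an estimated correlation). The ATP synthase gene atp-6 was lower, from 2442 ± 52.2 to 732 ± 51.95 FPKM (log2 -1.74 ± 0.16, limma adjusted p = 9.39e-04). FMRFamide-like neuropeptide genes were lower in 13 of 30 cases, 14 lower and 1 higher adjusted over the list alone, and 21 lower by edgeR. Without either aak(0) dauer library 3 were lower, and without daf-2 hzl-1 dauer library 2 a pair of them was higher. The median FMRFamide-like gene had a log2 change of -0.70, -1.11 relative to all genes (limma camera adjusted p = 1.2e-13, adjusted p = 0.74 with an estimated correlation). The gene flp-13, for a peptide that quiets behaviour, was lower, from 57.7 ± 5.03 to 15.1 ± 3.66 FPKM (log2 -1.89 ± 0.26, limma adjusted p = 0.00332). Neuron markers had 2 higher and 2 lower genes of 27, the same adjusted over the list alone, and by edgeR 2 and 9. The lower genes numbered 1 without either daf-2 hzl-1 dauer library and 0 without either aak(0) dauer library, and 1 was higher without aak(0) dauer library 2. The median neuron marker had a log2 change of -0.11, -0.52 relative to all genes (limma camera adjusted p = 3.5e-04, adjusted p = 0.79 with an estimated correlation). Cytosolic ribosomal protein genes had 1 higher of 78, 0 adjusted over the list alone, with 1 at unadjusted p < 0.05 by limma, and 0 by edgeR with 11. The median ribosomal protein gene had a log2 change of -0.22, -0.63 relative to all genes (limma camera adjusted p = 1.4e-11, adjusted p = 0.92 with an estimated correlation).

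Somatic lists higher in aak(0) dauers included the cuticle and the gut. Molting and larval cuticle genes were higher in 19 of 26 cases, 23 adjusted over the list alone and 11 by edgeR. There were 12 without daf-2 hzl-1 dauer library 1 and 6 without either aak(0) dauer library. The median molting gene had a log2 change of 2.64, 2.24 relative to all genes (limma camera adjusted p = 2.0e-05, adjusted p = 0.78 with an estimated correlation). Their collagen gene dpy-5 was higher, from 0.20 ± 0.156 to 49.04 ± 0.58 FPKM (log2 5.39 ± 0.32, limma adjusted p = 1.97e-04). Innate immunity genes were higher in 19 of 30 cases, 21 adjusted over the list alone and 17 by edgeR, and in 12 and 11 without aak(0) dauer library 1 and 2. The median immunity gene had a log2 change of 1.995, 1.59 relative to all genes (limma camera adjusted p = 1.5e-04, adjusted p = 0.78 with an estimated correlation). The infection response gene irg-4 was higher, from 0.175 ± 0.163 to 27.4 ± 2.17 FPKM (log2 4.5997 ± 0.25, limma adjusted p = 1.81e-04). Intestine markers were higher in 16 of 24 cases, 17 adjusted over the list alone. The median intestine marker had a log2 change of 1.24, 0.83 relative to all genes (limma camera adjusted p = 4.2e-04, adjusted p = 0.84 with an estimated correlation). Insulin-like peptide genes were split, 3 higher and 5 lower of 24, 7 and 7 adjusted over the list alone. The lower genes numbered 3 without daf-2 hzl-1 dauer library 1 and 0 without either aak(0) dauer library. The median insulin-like gene had a log2 change of -0.06, -0.46 relative to all genes (limma camera adjusted p = 0.016, adjusted p = 0.78 with an estimated correlation). Dauer cuticle genes were not called as a list, with 1 of 7 higher, 7 adjusted over the list alone and 0 by edgeR. Of them 5 were higher without daf-2 hzl-1 dauer library 1, where their median FPKM was 2.31 against 272 in library 2, 7 without library 2 and 0 without either aak(0) dauer library. The median dauer cuticle gene had a log2 change of 4.05, 3.64 relative to all genes (limma camera adjusted p = 0.27, adjusted p = 0.98 with an estimated correlation).

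In post-dauers the same comparison asked what differs after recovery. The neuropeptide-like gene nlp-39 was higher in libraries labelled aak(0), from 3.79 ± 2.17 to 369 ± 5.81 FPKM (log2 6.35 ± 0.41, limma adjusted p = 0.00177). The linker histone gene hil-7 was higher, from 1.49 ± 1.15 to 66.7 ± 15.3 FPKM (log2 4.83 ± 0.42, limma adjusted p = 0.00296). The ubiquitin ligase component gene skr-8 was higher, from 1.28 ± 0.325 to 53.4 ± 0.636 FPKM (log2 4.58 ± 0.22, limma adjusted p = 7.51e-04). The lectin gene clec-266 was higher, from 9.44 ± 6.80 to 227 ± 13.5 FPKM (log2 4.62 ± 0.44, limma adjusted p = 0.0043), a value left uncertain by 193 nt of exon shared with kqt-1 on the opposite strand. The early embryo gene pes-2.2 was listed at 0 in daf-2 hzl-1 and stood at 28.3 ± 14.7 FPKM in aak(0). Lower in aak(0) were yolk transcripts such as vit-3, from 2515 ± 219.6 to 394 ± 34.9 FPKM (log2 -2.67 ± 0.16, limma adjusted p = 0.0015). Reads shared among vit genes, and 171 nt of exon that vit-3 shares with T27A10.8 on the opposite strand, leave the single vit values uncertain. Lower by limma was vit-1, from 1014 ± 36.5 to 149 ± 3.44 FPKM (log2 -2.75 ± 0.18, limma adjusted p = 0.00177), but edgeR did not call it (adjusted p = 0.0630). The superoxide dismutase gene sod-5 was lower, from 73.6 ± 53.3 to 5.03 ± 2.64 FPKM (log2 -3.49 ± 0.62, limma adjusted p = 0.0311). Its adjusted p was 0.162 and 0.0506 without daf-2 hzl-1 post-dauer library 1 and 2 and 0.117 without aak(0) library 2. Limma called 716 of 15365 genes (648 higher, 68 lower), 661 of them by more than log2 1, and edgeR 711 (577 higher, 134 lower). The share of higher calls was 90.5% as deposited, 79.3% with RLE and 70.1% by DESeq2. Without daf-2 hzl-1 post-dauer library 1 or 2 limma called 90 or 175 genes. Without aak(0) post-dauer library 1 it called 1721, 38.3% of them higher, and without library 2 it called 342.

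All 6 vitellogenins were lower in aak(0) post-dauers when adjusted over the list alone, 4 over all genes and 2 by edgeR. The median vitellogenin gene had a log2 change of -2.35, -2.48 relative to all genes (limma camera adjusted p = 8.1e-11, adjusted p = 0.60 with an estimated correlation). Vitellogenins took 7.63% and 8.31% of reads in daf-2 hzl-1 and 2.01% and 1.55% in aak(0). Early embryo zygotic genes were higher in 4 of 9 cases, 5 adjusted over the list alone and 6 by edgeR, and in 1 without either daf-2 hzl-1 post-dauer library. The median early embryo gene had a log2 change of 0.75, 0.62 relative to all genes (limma camera adjusted p = 0.00462, adjusted p = 0.60 with an estimated correlation). The very early embryonic transcript vet-6 was higher, from 0.285 ± 0.0354 to 8.12 ± 0.948 FPKM (log2 2.82 ± 0.22, limma adjusted p = 0.00241). The T-box gene tbx-11 was higher, from 0.85 ± 0.0566 to 5.49 ± 0.672 FPKM (log2 1.81 ± 0.21, limma adjusted p = 0.0080). Without either daf-2 hzl-1 post-dauer library fewer of these genes were called, and tbx-11 was not. Oocyte and eggshell genes were not called as a list, with 1 of 30 higher, and 1 higher and 1 lower adjusted over the list alone. Without aak(0) post-dauer library 1 there were 3 lower. The median oocyte gene had a log2 change of 0.01, -0.12 relative to all genes (limma camera adjusted p = 0.087, adjusted p = 0.93 with an estimated correlation). Major sperm proteins were higher in 2 of 28 cases, 21 adjusted over the list alone, and 0 by edgeR with 11 at unadjusted p < 0.05. With any 1 of the post-dauer libraries left out the count was 0 by limma. The median major sperm protein had a log2 change of 0.79, 0.66 relative to all genes (limma camera adjusted p = 1.0e-06, adjusted p = 0.78 with an estimated correlation).

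Insulin-like peptide genes were higher in 6 of 24 cases in aak(0) post-dauers, 13 adjusted over the list alone and 4 by edgeR. The median insulin-like gene had a log2 change of 0.89, 0.75 relative to all genes (limma camera adjusted p = 4.0e-06, adjusted p = 0.60 with an estimated correlation). The agonist gene ins-7 was higher, from 7.45 ± 0.721 to 32.5 ± 4.95 FPKM (log2 1.98 ± 0.22, limma adjusted p = 0.00719). Without daf-2 hzl-1 post-dauer library 1 or 2 the higher insulin-like genes numbered 0, and ins-7 had an adjusted p of 0.0676 or 0.0665. Innate immunity genes were higher in 8 of 30 cases, 14 adjusted over the list alone and 7 by edgeR. There were 0 and 2 without daf-2 hzl-1 post-dauer library 1 and 2 and 4 without either aak(0) post-dauer library. The median immunity gene had a log2 change of 0.91, 0.78 relative to all genes (limma camera adjusted p = 3.9e-05, adjusted p = 0.60 with an estimated correlation). The lysozyme gene lys-8 was higher, from 189 ± 16.8 to 441 ± 20.6 FPKM (log2 1.22 ± 0.14, limma adjusted p = 0.00769), with an adjusted p of 0.0847 without daf-2 hzl-1 post-dauer library 1. Mitochondrially encoded genes were higher in 4 of 14 cases, 13 adjusted over the list alone and 1 by edgeR. There were 0 without either daf-2 hzl-1 post-dauer library and 2 without aak(0) library 2. The median mitochondrial gene had a log2 change of 0.76, 0.63 relative to all genes (limma camera adjusted p = 1.2e-05, adjusted p = 0.60 with an estimated correlation). Effects of aak(0) in dauers and in post-dauers shared no library and had a Pearson r of 0.165 and a Spearman rho of 0.162 over the tested genes. Both stages called 211 genes higher, against 165 for independent lists, and 11 lower, against 2.4. Opposite calls numbered 47, against 40.6.

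The interaction asked which genes change differently between the stages in the 2 backgrounds. Oocyte and eggshell genes rose less in aak(0) in 24 of 30 cases, 28 adjusted over the list alone and 24 by edgeR. The median oocyte gene had a log2 change of -2.81, -2.48 relative to all genes (limma camera adjusted p = 1.3e-17, adjusted p = 0.23 with an estimated correlation). Among them were cbd-1 (log2 -5.36 ± 0.23) and mex-6 (log2 -3.095 ± 0.18, limma adjusted p = 0.0017 for each). Major sperm proteins rose less in 25 of 28 cases, 27 adjusted over the list alone and 22 by edgeR. Some left-out libraries gave fewer. For oocyte and MSP genes the median aak(0) effect was log2 2.72 and 3.25 in dauers and 0.01 and 0.79 in post-dauers. Higher dauer levels thus gave the smaller rises. The median major sperm protein had a log2 change of -2.53, -2.19 relative to all genes (limma camera adjusted p = 1.9e-13, adjusted p = 0.58 with an estimated correlation). Mitochondrially encoded genes differed upward in 14 of 14 cases, 14 adjusted over the list alone and 12 by edgeR. There were 6 without either aak(0) dauer library and 7 without daf-2 hzl-1 post-dauer library 1. The median mitochondrial gene had a log2 change of 2.28, 2.61 relative to all genes (limma camera adjusted p = 1.3e-14, adjusted p = 0.28 with an estimated correlation). The ATP synthase gene atp-6 was among these (log2 2.48 ± 0.23, limma adjusted p = 0.00268). FMRFamide-like neuropeptide genes fell less in 12 of 30 cases, 17 adjusted over the list alone and 14 by edgeR. There were 2 and 3 without aak(0) dauer library 1 and 2, and 6 without daf-2 hzl-1 post-dauer library 2. The median FMRFamide-like gene had a log2 change of 0.996, 1.33 relative to all genes (limma camera adjusted p = 3.6e-11, adjusted p = 0.58 with an estimated correlation). The neuropeptide gene flp-11 fell less (log2 1.97 ± 0.25, limma adjusted p = 0.00628). Limma called 1743 of 15365 genes (544 upward, 1199 downward), 1663 of them by more than log2 1, and edgeR 2219 (891 upward, 1328 downward). The share of upward calls was 31.2% as deposited and 45.8% with FPKM divided by TMM factors, with the median gene at log2 -0.34 and -0.10. Without aak(0) dauer library 1 or 2 limma called 360 or 426 genes, and without daf-2 hzl-1 post-dauer library 1 or 2 it called 512 or 552. Without daf-2 hzl-1 dauer library 2 it called 2848, and without aak(0) post-dauer library 1 it called 3896.

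Vitellogenins rose less in aak(0) in 4 of 6 cases, 6 adjusted over the list alone and 1 by edgeR. The median vitellogenin gene had a log2 change of -2.73, -2.40 relative to all genes (limma camera adjusted p = 1.2e-04, adjusted p = 0.58 with an estimated correlation). The yolk gene vit-3, whose single value is uncertain, rose less (log2 -2.85 ± 0.23, limma adjusted p = 0.00187). DNA replication and cell cycle genes rose less in 15 of 34 cases, 21 adjusted over the list alone and 7 by edgeR. There were 4 without either aak(0) dauer library, and 6 and 5 without daf-2 hzl-1 post-dauer library 1 and 2. The median replication gene had a log2 change of -0.99, -0.66 relative to all genes (limma camera adjusted p = 1.8e-06, adjusted p = 0.58 with an estimated correlation). Their member rnr-2 was called with each library left out (log2 -2.96 ± 0.18, limma adjusted p = 0.0017). P granule genes rose less in 11 of 21 cases, 13 adjusted over the list alone and 7 by edgeR. There were 4 and 5 without aak(0) dauer library 1 and 2, and 5 and 6 without daf-2 hzl-1 post-dauer library 1 and 2. The median P granule gene had a log2 change of -1.33, -0.998 relative to all genes (limma camera adjusted p = 1.2e-05, adjusted p = 0.58 with an estimated correlation). Molting and larval cuticle genes differed downward in 9 of 26 cases and upward in 2, 11 and 2 adjusted over the list alone. Without daf-2 hzl-1 dauer library 2, 21 differed downward. The median molting gene had a log2 change of -2.33, -1.999 relative to all genes (limma camera adjusted p = 0.00234, adjusted p = 0.79 with an estimated correlation). The collagen gene dpy-5 differed downward (log2 -5.35 ± 0.46, limma adjusted p = 0.00218). The collagen gene dpy-17 differed upward (log2 3.47 ± 0.28, limma adjusted p = 0.00191), through aak(0) post-dauers at 99.7 ± 6.70 FPKM against 5.85 ± 1.07 in daf-2 hzl-1. Among targeted genes aak-1 differed (log2 -1.86 ± 0.34, limma adjusted p = 0.0196), with an adjusted p of 0.101 and 0.0520 without aak(0) dauer library 1 and 2 and of 0.0876 and 0.0825 without daf-2 hzl-1 post-dauer library 1 and 2. The interaction for aak-2 was not called by limma (log2 -1.06 ± 0.28, adjusted p = 0.0579), except without daf-2 hzl-1 dauer library 2 (log2 -1.21, adjusted p = 0.0416).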

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

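The tests of explanations in this part and those by edgeR were chosen only after the result was seen, apart from the thinning of the reads by edgeR, whose prediction was written before. A test of the interaction marked the results of this part, since it found the change from dauer to post-dauer to differ between the backgrounds.

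The interaction was called for 1743 genes by limma, and for 55 of the 106 genes named for a stage comparison. Upward, the fitted interaction values were log2 4.08 for the linker histone gene hil-3 and log2 3.95 for his-24, another linker histone gene. The nematode-specific peptide gene nspe-7 had log2 3.61. Fitted values of genes with a group listed at 0 rest on the pseudocount and are no measured change. They were log2 4.62 for nlp-39 (0 in daf-2 hzl-1 dauers), 4.58 for sls-2.5 (0 in 3 of the groups) and 3.62 for pes-2.2 (0 in daf-2 hzl-1 post-dauers). None of these had support from edgeR, which did not call nlp-39 (adjusted p = 0.80) and did not test the other 2. Downward, the fitted values were log2 -8.23 for pud-2.1 and -6.39 for pud-3, genes of proteins abundant in daf-2 mutants, and -5.79 for sdz-24. The collagen gene col-17 had log2 -6.20, and the collagen gene sqt-1, listed at 0 in daf-2 hzl-1 dauers, had a fitted -5.65 that rests on the pseudocount as well. The antimicrobial peptide gene cnc-5 had log2 -5.96.

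Among germline lists, the median interaction was log2 -2.81 for oocyte and eggshell genes and -2.53 for major sperm proteins. It was -1.29 for other sperm genes and -1.33 for P granule genes. For DNA replication and cell cycle it was -0.99, and for the small RNA pathway -0.86. Among lists of the soma and the embryo, it was log2 -2.73 for vitellogenins, -1.14 for intestine markers, -1.09 for fatty acid and fat synthesis, -2.33 for molting and larval cuticle and 1.099 for early embryo zygotic genes. Upward medians were log2 2.28 for mitochondrially encoded genes, 1.25 for insulin-like peptides, 0.996 for FMRFamide-like neuropeptides, 0.30 for neuron markers, 0.24 for cytosolic ribosomal proteins and 0.12 for the nuclear-encoded respiratory chain. With an estimated correlation the limma camera adjusted p of these lists ran from 0.23 to 0.86, so none was called that way.

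Oocyte and major sperm protein transcripts were higher in aak(0) dauers. Adult hermaphrodites among the dauers would bring yolk transcripts, but the vitellogenins stood at 0.0903% of their aak(0) post-dauer FPKM and the oocyte genes at 23.3%, which argues against that explanation. Adult cuticle genes stood at 2.63%. Some adult transcripts were higher in aak(0) dauer library 1 alone, with col-119 at 19.4 FPKM against 0.05 in library 2 and vit-6 at 2.93 against 0.13. The uterine gene ule-4 stood at 22.8 and 19.5 in these libraries, against 0.63 and 0 in daf-2 hzl-1 dauers, so a few adults in either are not excluded. The oocyte median was 45.1 and 45.9 FPKM in these libraries. Scaling of the libraries is argued against as well, since the 27 oocyte and eggshell genes called higher were the same by edgeR with TMM, with a list median of log2 2.98. Larvae of another stage or dauers of another age may be among the aak(0) animals, since 19 of 26 molting and larval cuticle genes were higher too. That stays open, since 11 were higher by edgeR, 12 without daf-2 hzl-1 dauer library 1 (median FPKM 0.255 against 4.47 in library 2) and 6 without either aak(0) dauer library. Loss of AMPK itself stays open and was not tested apart from these.

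Calls in aak(0) dauers were mostly higher, 87.6% as deposited. Reads taken by rRNA are argued against, since 84.95% of calls were higher with FPKM rescaled to reads outside rRNA. Deeper sequencing of the aak(0) dauers is argued against too, since after thinning to the smallest library 87.8% of limma calls were higher, and 64.5% by edgeR, against 64.9% before. Library composition other than rRNA cannot be told apart from a true shift for these calls, since 65.3% were higher with FPKM divided by TMM factors and the labels name no spiked RNA that would fix the scale. Loss of AMPK stays open here as well.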

How the results depend on the processing

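The alternatives chosen only after the result was seen were edgeR with TMM, both limma rescalings, the crossed pairing and camera on recovered reads. With n = 2 per group a left-out library leaves a lone sample, which is assumed to vary like the other groups, and low depth limits genes such as hzl-1. Among named genes 3419 results kept direction and call under the settings other than leaving out a library, 135 lost the call, 38 gained it and 20 turned direction, and with a library left out these numbers were 1393, 173, 10 and 6. Counts of called genes in both stage comparisons kept within 1.5 times the reported count in each setting with all libraries of the comparison, and the replicate block moved no count by over 1.5 times other than those given.

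Gene lists called numbered 22, 19, 14, 13 and 17 in the comparisons in the order of the report. With an estimated correlation 0 were called in each, and at unadjusted p < 0.05 there were 1, 1, 2, 2 and 3. Fry called 23, 22, 15, 5 and 13, and camera on reads 20, 20, 15, 12 and 16. Camera on reads lost insulin-like peptides (adjusted p = 0.0719) and dauer cuticle (0.0743) between stages in daf-2 hzl-1 and DAF-16 targets (0.0734) in aak(0). For aak(0) it lost P granule genes (0.0553) and insulin-like peptides (0.26) in dauers and the respiratory chain (0.23) in post-dauers, and for the interaction vitellogenins (0.0638). It gained 2 lists between stages in aak(0) and 3 in dauers. For aak(0) in post-dauers, 716 called genes became 1905 by edgeR with no filter, 1076 by DESeq2, 281 with the compared libraries alone, 367 with a replicate block and 601 with crossed pairing. For the interaction, 1743 became 3460 by edgeR with no filter and 1044 with the block. With a library left out, called genes ran from 8180 to 9852 and from 4964 to 8241 for the stage comparisons in daf-2 hzl-1 and aak(0), from 1305 to 5074 and from 90 to 1721 for aak(0) in dauers and post-dauers, and from 360 to 3896 for the interaction. Fewer libraries and fewer residual degrees of freedom enter those fits, and otherwise the cause was not tested.

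In dauers the small effect of aak(0) turned negative for aak-2, with log2 -0.25 by edgeR with TMM, -0.34 with RLE, -0.26 with no filter, -0.33 by DESeq2 and -0.24 with FPKM divided by TMM factors, and for daf-2 with -0.12, -0.22, -0.14, -0.21 and -0.15 in that order. For rpl-41.1 it turned to -0.045, -0.13, -0.061 and -0.12 in the edgeR and DESeq2 settings of that order. In post-dauers aak-2 passed the threshold, with log2 -1.02 by edgeR with TMM, -1.07 with RLE, -0.93 with library totals, -1.07 with no filter, -1.07 by DESeq2, -1.02 with FPKM divided by TMM factors and -0.90 rescaled to reads outside rRNA. Its interaction passed with library totals (-1.06) and outside rRNA (-0.99). The interaction of vet-6, listed at 0 in daf-2 hzl-1 dauers, turned to fitted values of log2 -1.65 by edgeR with TMM, -1.59 with RLE, -1.62 with library totals, -1.69 with no filter and -0.39 by DESeq2, none a measured change, and that of hzl-1 to -0.13 with a pseudocount of 0.1. The cause was not tested.

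With a library left out, log2 ranges were -0.052 to 0.31 for aak-2 in dauers, -0.071 to 0.66 and 0.31 to 1.13 for hzl-1 between stages in daf-2 hzl-1 and aak(0), and -1.35 to -0.14 for daf-2 between stages in aak(0). For aak(0) in post-dauers daf-2 ran from -0.85 to 0.37. Interactions ran from -2.12 to -1.60 for aak-1, from -1.25 to -0.88 for aak-2, from -0.29 to 0.83 for hzl-1 and from -1.06 to 0.15 for daf-2. Correlation of the stage changes, 0.809, was 0.658 by edgeR with no filter, 0.692 by DESeq2 and 0.772 with a pseudocount of 0.1, and 0.748 to 0.838 with a library left out. Correlation of the aak(0) effects, 0.165, was 0.143 by edgeR with TMM, 0.143 with RLE, 0.142 with library totals, 0.0991 with no filter, 0.107 by DESeq2, 0.176 with FPKM divided by TMM factors and 0.197 with the compared libraries alone, and 0.143 to 0.174 with a library left out. The cause was not tested.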

Other observations

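The tests by edgeR and those of explanations for the vitellogenin and early embryo genes were chosen only after the result was seen. Metabolic and small RNA lists changed between the stages in daf-2 hzl-1. Fatty acid and fat synthesis genes rose in 16 of 24 cases and fell in 2, 18 and 2 adjusted over the list alone, and 1 fell with any library left out. The median fat synthesis gene had a log2 change of 1.25, 0.91 relative to all genes (limma camera adjusted p = 0.00441, adjusted p = 0.68 with an estimated correlation). The elongase gene elo-6 rose from 26.8 ± 5.08 to 368 ± 33.4 FPKM (log2 3.74 ± 0.19, limma adjusted p = 1.92e-05). In aak(0) dauers 13 of these genes were higher, 16 adjusted over the list alone, and 7 without either aak(0) dauer library. The median fat synthesis gene had a log2 change of 0.97, 0.56 relative to all genes (limma camera adjusted p = 0.011, adjusted p = 0.92 with an estimated correlation). There elo-6 was higher, from 26.8 ± 5.08 to 124 ± 6.23 FPKM (log2 2.17 ± 0.19, limma adjusted p = 7.45e-04). Small RNA pathway genes rose in 30 of 42 cases and fell in 1 in daf-2 hzl-1, the same adjusted over the list alone. The median small RNA gene had a log2 change of 1.56, 1.23 relative to all genes (limma camera adjusted p = 7.3e-05, adjusted p = 0.67 with an estimated correlation). The Argonaute gene wago-1 rose from 12.33 ± 1.22 to 265 ± 21.4 FPKM (log2 4.32 ± 0.14, limma adjusted p = 5.63e-06). Histone methylation genes rose in 20 of 33 cases and fell in 4, the same adjusted over the list alone, and 2 fell without dauer library 2. The median histone methylation gene had a log2 change of 0.96, 0.63 relative to all genes (limma camera adjusted p = 0.0283, adjusted p = 0.68 with an estimated correlation). The methyltransferase gene set-4 rose from 11.7 ± 1.22 to 71.5 ± 12.04 FPKM (log2 2.51 ± 0.17, limma adjusted p = 5.05e-05). Cell cycle inhibitors and quiescence genes rose in 10 of 12 cases and fell in 1, the same adjusted over the list alone. The median gene of this list had a log2 change of 1.51, 1.17 relative to all genes (limma camera adjusted p = 0.0101, adjusted p = 0.48 with an estimated correlation). DAF-16 target genes fell in 14 of 22 cases and rose in 4 in aak(0), the same adjusted over the list alone. The median DAF-16 target had a log2 change of -1.30, -1.32 relative to all genes (limma camera adjusted p = 0.0437, adjusted p = 0.75 with an estimated correlation).

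In aak(0) post-dauers chaperone genes were lower in 5 of 21 cases, 8 lower and 3 higher adjusted over the list alone, and in 0 without either daf-2 hzl-1 post-dauer library or aak(0) library 2. The median chaperone gene had a log2 change of -0.46, -0.59 relative to all genes (limma camera adjusted p = 0.00226, adjusted p = 0.60 with an estimated correlation). The mitochondrial chaperone gene hsp-60 was lower, from 161 ± 15.5 to 72.8 ± 4.2 FPKM (log2 -1.13 ± 0.16, limma adjusted p = 0.0165). Its adjusted p was 0.140 and 0.0845 without daf-2 hzl-1 post-dauer library 1 and 2 and 0.0517 without aak(0) library 2. Xenobiotic detoxification genes were higher in 6 of 26 cases, 9 adjusted over the list alone, and in 0 and 1 without daf-2 hzl-1 post-dauer library 1 and 2. The median detoxification gene had a log2 change of 0.38, 0.25 relative to all genes (limma camera adjusted p = 0.0497, adjusted p = 0.94 with an estimated correlation). Respiratory chain genes were called as a list with 0 of 37 members called by limma, 17 at unadjusted p < 0.05 and 0 by edgeR with 1. The median respiratory chain gene had a log2 change of 0.40, 0.27 relative to all genes (limma camera adjusted p = 0.00558, adjusted p = 0.94 with an estimated correlation). Glyoxylate, gluconeogenesis and trehalose genes were called as a list with 0 of 20 members called by limma, 3 at unadjusted p < 0.05, and 1 by edgeR, and 2 were lower without aak(0) post-dauer library 1. The median glyoxylate gene had a log2 change of -0.21, -0.34 relative to all genes (limma camera adjusted p = 0.0297, adjusted p = 0.94 with an estimated correlation). P granule genes were lower as a list with 0 of 21 members called by limma or edgeR, 6 and 5 at unadjusted p < 0.05. The median P granule gene had a log2 change of -0.26, -0.39 relative to all genes (limma camera adjusted p = 5.1e-05, adjusted p = 0.60 with an estimated correlation). Germline stem cell and meiosis genes were lower as a list with 0 of 38 members called by limma or edgeR, 6 and 12 at unadjusted p < 0.05, and 7 were lower without aak(0) post-dauer library 1. The median germline gene had a log2 change of -0.24, -0.37 relative to all genes (limma camera adjusted p = 8.0e-05, adjusted p = 0.67 with an estimated correlation). The list medians were 50.1 and 29.1 FPKM in aak(0) libraries 1 and 2 for germline genes and 48.2 and 31.5 for P granule genes, so library 2 stood apart, and without it the median log2 changes were -0.10 and -0.22.

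Other lists were not called by limma camera in any comparison, and their counts were the same adjusted over the list alone unless given. Between the stages in daf-2 hzl-1, lipolysis and beta-oxidation genes had 12 of 21 higher and 2 lower (adjusted p = 0.12). Autophagy and lysosome genes had 5 of 25 higher and 8 lower (adjusted p = 0.25), with 2 higher without dauer library 2 or post-dauer library 2. Muscle markers had 7 of 25 higher and 11 lower, 8 and 11 adjusted over the list alone (adjusted p = 0.27), with 11 higher without dauer library 2 and 3 without post-dauer library 2. Hypodermis and seam markers had 6 of 19 higher and 8 lower, and somatic gonad and vulva markers 6 of 19 higher and 7 lower (adjusted p = 0.42 for each). AMPK subunit and upstream kinase genes had 5 of 13 higher and 5 lower (adjusted p = 0.597). Unfolded protein and oxidative stress genes had 8 of 25 higher and 8 lower (adjusted p = 0.705).

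Vitellogenins were lower and early embryo genes higher in aak(0) post-dauers. A lower share of intestine is argued against, since the lower quartile of the other intestine markers was log2 -0.062 while the vitellogenin median was -2.35. Reads moving between vit genes are argued against, since the summed vitellogenin share was 4.48 times lower in aak(0), and reads freed by that drop shift other genes by log2 0.094, less than the rise of the called early embryo genes. Animals of another reproductive age, or holding more embryos, stay open, since higher early embryo genes are part of the pattern and cannot test this. Loss of AMPK stays open and was not tested apart from this.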
